A study of Mus musculus with 9 samples.

How the data were processed

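RNA-seq was measured in 9 libraries of mouse embryonic fibroblasts, 3 in each of 3 groups, on day 4 after infection with an empty lentivirus or one carrying p21 or p16. The deposited values are raw read counts per gene symbol in 1 table. Per the submitters' processing notes, reads were aligned to mm10 (GRCm38) with TopHat2 2.0.14 and Bowtie2 2.2.6 and counted with featureCounts 1.4.6 of Subread, and the deposited counts carry no further normalization. The gene annotation and the strand setting of the counting are not given. The library kit named in the labels keeps no strand, so reads of genes that overlap on opposite strands cannot be separated. The labels do not describe the replicates as separate cultures or animals. If they were not, the p-values measure the spread between samples only.

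Library totals ran from 44455730 to 63152239 counts. The common dispersion was 0.00533, a biological coefficient of variation of 7.30%. Between libraries of a group the squared differences exceeded counting error by 5.27 to 16.9 times (chi-squared per degree of freedom). This ratio is taken over many genes together, and for genes with few counts the depth can limit the precision. Of 24062 symbols in the table, 22750 matched GENCODE M21, from which coordinates, lengths and exon overlaps were taken.

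Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 14223, and libraries were scaled by TMM. All libraries entered 1 quasi-likelihood fit by group, with 6 residual degrees of freedom. Its two-sided F test was applied to p21 against the empty vector, p16 against the empty vector and p21 against p16, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled totals, except the summed leukocyte markers, which use the library totals alone. Log2 CPM for principal components used a prior count of 2.

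The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule takes Cdkn1a and Cdkn2a, the 10 largest rises and 10 largest falls per comparison, and up to 4 members of each list with the smallest adjusted p. The largest changes had to pass the test, have a mean log2 CPM of at least 1 and show no overlap between the libraries of both groups, and predicted, mitochondrial and histone genes were left out. The 28 lists cover cell cycle, secretory, matrix, contractile, immune, metabolic and stress genes, RNA quality and markers of other cell types, and hold neither delivered gene. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. With the estimated correlation the G2/M and mitosis and the smooth muscle lists passed with p21 and in p21 against p16. The S phase, secretory factor and smooth muscle lists passed with p16. No mitochondrially encoded transcript is in the table, and of the red cell list 1 gene, Alas2, was tested, so these lists had no test.

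The agreement of the p21 and p16 effects was set beside 50 simulations of unchanged groups against the same controls, since both comparisons share the control libraries. Alternatives were DESeq2 size factors (the RLE method), library totals only, both delivered genes left out, no filter, the Wald test of DESeq2 1.42.0, limma-voom, fits of only the 2 groups compared, the replicate number as a block, glmTreat against a 1.5-fold change, and each library left out in turn. A fit of replicates 1 and 2 alone was added after seeing the data, because the replicate 3 libraries stood apart. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures.

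The labels do not explain the replicate numbers, so pairing was checked. After removal of the group means, libraries with the same number correlated across genes at r = 0.126 to 0.361, and others at -0.246 to 0.106. All 9 libraries correlated best with their own number in both other groups, so the numbers pair the samples. The main fit was fixed before this check and has no block, so differences between the replicate numbers enter its spread. With the block more genes passed: 6856 against 5681 with p21, 3044 against 1616 with p16 and 3214 against 1858 in p21 against p16. Blocked values stand beside the list results that they change and beside some of the named genes, and the closing section counts the others.

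The fit was checked on simulated data with known changes in the p21 group. It recovered 40.3% of genes changed by 0.3 on the log2 scale, 72.7% at 0.6 and 81.8% at 1, and 6% of the 150 genes called were unchanged. The simulation also shifted the lysosome list by 0.2, held far fewer changed genes than the p21 data gave calls, and had no pairing by replicate. These shares therefore do not give the power of the real fits. Of named genes, Tagln (55.0%), Ccnd1, Ctsd, Icam1 (20.2%), Sqstm1 (20.6%), Gas1 (19.9%), Hspa1a (19.0%) and E2f8 (15.7%) are among those that share over 15% of their exon bases with another annotated gene. The p16 libraries may have been made apart from the rest, which the labels do not say, and such a batch could not be told apart from p16.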

Results

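RNA-seq measured the transcriptome of mouse embryonic fibroblasts (MEFs, primary connective tissue cells grown from mouse embryos, here of the C57BL/6 strain) after lentiviral delivery of 1 of 2 inhibitors of cyclin-dependent kinases. The p21 group received Cdkn1a, which encodes the inhibitor p21, the p16 group received Cdkn2a, which encodes the inhibitor p16, and the control group received an empty vector. RNA was taken on day 4, and the labels call the cells of all 3 groups non-senescent. Each group held 3 libraries, and the labels do not say whether these came from separate embryos or cultures. The libraries held between 44455730 and 63152239 counted reads, and 14223 genes were tested. The first principal component held 35.4% of the variance and ordered the groups from the empty vector over p16 to p21. The second held 18.9% and set the replicate 3 libraries of all 3 groups apart. These replicate 3 libraries carried Xist, the X-inactivation transcript of female cells, at 181 to 251 CPM (counts scaled to a common library total), against at most 6.96 CPM in the replicate 1 and 2 libraries, so each group held 1 library with this transcript at a high level.

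The delivered genes were measured first, as a check of the labels. Cdkn1a, on chromosome 17 (29090976 to 29100727 in GRCm38, the build mm10), reached 1605 ± 172 CPM (SD, n = 3) in the p21 libraries against 360.2 ± 12.8 CPM (SD, n = 3) in the controls, a 4.46-fold difference. The log2 fold change was 2.16 ± 0.063 (SE), with an edgeR adjusted p of 2.09e-09. In the p16 libraries Cdkn1a stood at 373 ± 6.2 CPM, which did not pass the test against the controls (log2 fold change 0.049 ± 0.061, edgeR adjusted p = 0.672). Cdkn2a, on chromosome 4 (89274471 to 89294653), reached 1731 ± 179 CPM in the p16 libraries against 37.9 ± 3.86 CPM in the controls, 45.6-fold higher (log2 fold change 5.51 ± 0.090, edgeR adjusted p = 1.84e-12). It was also 1.23-fold higher in the p21 libraries, at 46.5 ± 2.21 CPM (edgeR adjusted p = 0.0111). The counts are per gene, so reads of the delivered and of the endogenous copy are summed, and the Cdkn2a row also sums the exons of its second product, Arf.

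**Figure D1:**
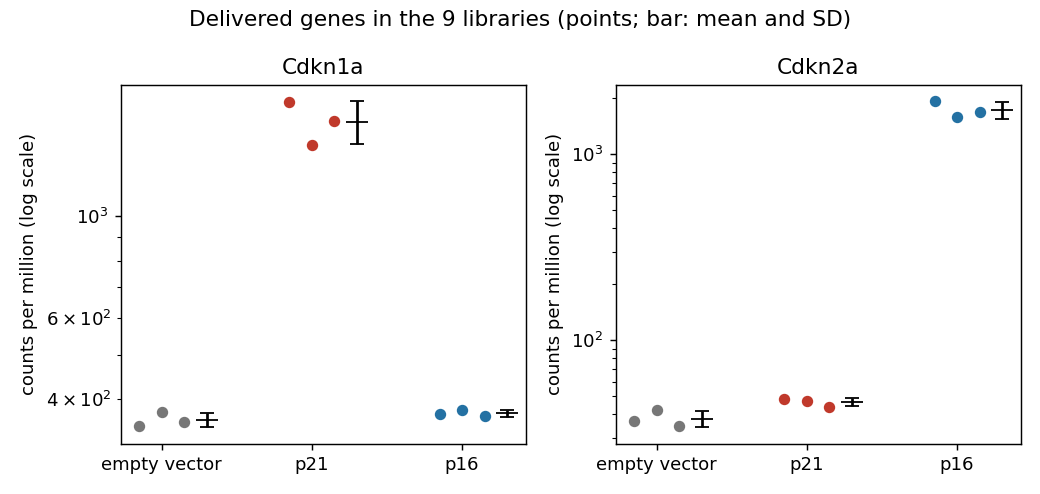
CPM of Cdkn1a (left) and Cdkn2a (right) on a log axis, with 1 point per library in the empty vector, p21 and p16 groups and the group mean and SD beside the points. The 3 p21 libraries lie above the other 6 for Cdkn1a, and the 3 p16 libraries lie above the other 6 for Cdkn2a.

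The comparison of p21 with the empty vector asks which transcripts differ once p21 is supplied. Most listed genes of cell division fell, and most listed contractile and lysosomal genes rose. The S phase and lysosome lists, however, were not called with an estimated correlation. All 40 tested genes of the G2/M and mitosis list fell, with a median log2 fold change of -0.95 (camera adjusted p = 7.96e-110, and adjusted p = 0.00866 with an estimated correlation), and all 40 were called when adjusted over the list alone. Among them were Ccna2, which encodes cyclin A2 (48.9 against 107 CPM, log2 fold change -1.12 ± 0.044), and the proliferation marker Mki67 (115 against 245 CPM, -1.09 ± 0.048). Of 39 S phase and DNA replication genes, 36 fell and 1 rose (36 and 2 adjusted over the list alone). Their median was -0.40 (camera adjusted p = 4.51e-20, but adjusted p = 0.0579 with an estimated correlation). The replication licensing factor Mcm5 changed by -0.54 ± 0.041. Of the 25 genes of the RB, E2F, cyclin and CDK inhibitor list, 6 rose and 12 fell, the same numbers adjusted over the list alone. As a list they were not called against the other genes (camera adjusted p = 0.0756, and 0.0278 without the filter on low counts), but were lower on balance by fry, which tests a list by itself (fry adjusted p = 0.00118). Ccnd2, which encodes cyclin D2, rose from 727 to 1241 CPM (0.77 ± 0.038), while E2f8, which encodes a repressor of the E2F family, changed by -0.92 ± 0.063.

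Smooth muscle and contractile genes were higher with p21: 17 of 22 rose and 0 fell, the same numbers adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 1.03e-20, and adjusted p = 0.00686 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, rose from 73.5 ± 4.98 to 153 ± 3.86 CPM, and Mylk, the kinase of the myosin light chain, changed by 0.84 ± 0.051. Among the 10 skeletal and cardiac muscle markers, the skeletal actin Acta1 rose from 132 ± 8.45 to 394 ± 31.8 CPM, the receptor subunit Chrna1 changed by 0.91 ± 0.18, and no other member passed the test, also adjusted over the list alone (median 0.57, camera adjusted p = 0.00126, but adjusted p = 0.0714 with an estimated correlation). The cardiac actin Actc1 (1.06 ± 0.44, edgeR adjusted p = 0.0732) passed with the replicate block (edgeR adjusted p = 0.0242), only the 2 groups fitted (0.0415), replicates 1 and 2 alone (0.0250) and without control replicate 3 (0.0347). Of 25 genes of the TGF-beta response, 10 rose and 3 fell, in both adjustments (camera adjusted p = 0.00979, but adjusted p = 0.243 with an estimated correlation). Inhba, an activin subunit, changed by 0.58 ± 0.050. Extracellular matrix genes went both ways, 20 up and 13 down of 49, also adjusted over the list alone (camera adjusted p = 0.217). The fibronectin gene Fn1 changed by 0.58 ± 0.046 and Col6a2, a collagen VI chain, by -0.67 ± 0.040.

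Of 37 lysosome genes, 31 rose and 0 fell (35 and 0 adjusted over the list alone), with a median log2 fold change of 0.36 (camera adjusted p = 5.34e-20, but adjusted p = 0.0598 with an estimated correlation). The protease gene Ctsd rose from 575 to 916 CPM (0.67 ± 0.038), of whose exon bases 31.5% are shared with another annotated gene on its strand. Of 47 senescence-associated secretory factors, 22 rose and 4 fell (23 and 5 adjusted over the list alone, camera adjusted p = 3.58e-05, but adjusted p = 0.0598 with an estimated correlation). Timp2 and Timp1, inhibitors of metalloproteinases, changed by 0.53 ± 0.040 and 0.61 ± 0.056, whereas Igfbp5, which binds insulin-like growth factors, fell from 186 to 84.1 CPM (-1.14 ± 0.092). Of 15 complement genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.0123, but adjusted p = 0.225 with an estimated correlation). Clu, which encodes clusterin, changed by 0.79 ± 0.14. Of 19 chemokine genes, 3 rose and 0 fell, in both adjustments (camera adjusted p = 0.342). These were Ccl17 at 0.98 ± 0.25, Ccl20 at 1.13 ± 0.30 and Cxcl14, which went from 22.8 ± 3.09 to 30.8 ± 5.04 CPM (0.44 ± 0.12, edgeR adjusted p = 0.0137). The call of Cxcl14 was lost without control replicate 3 or p21 replicate 1 (highest edgeR adjusted p = 0.0749). Markers of macrophages and other leukocytes moved with these groups. Scaled by library totals alone, their summed level was 29.1 to 46.6 CPM in the controls. It was 47.6 to 66.1 CPM with p21 and 37.5 to 66.8 CPM with p16. In the p21 comparison 7 of 18 such markers rose and 0 fell, in both adjustments, with a median of 0.77 (camera adjusted p = 0.0123, but adjusted p = 0.564 with an estimated correlation and 0.0703 without p21 replicate 3).

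Cholesterol synthesis genes were lower with p21: 18 of 24 fell and 0 rose (19 and 0 adjusted over the list alone, camera adjusted p = 1.76e-06, but adjusted p = 0.174 with an estimated correlation). Srebf2, the transcription factor that drives the pathway, changed by -0.30 ± 0.033 and the synthase gene Lss by -0.47 ± 0.053. Of 26 NRF2 and oxidative stress genes, 18 rose and 5 fell (19 and 5 adjusted over the list alone, camera adjusted p = 8.69e-04, but adjusted p = 0.212 with an estimated correlation). Hmox1, which encodes heme oxygenase, rose from 89.0 to 191 CPM (1.10 ± 0.053). Ribosomal protein genes, a list fixed beforehand for RNA quality, fell in 40 of 50 cases and rose in 0, by small amounts (41 and 0 adjusted over the list alone, median -0.14, camera adjusted p = 1.43e-06, but adjusted p = 0.482 with an estimated correlation). The data hold no direct measure of RNA quality, so this fall does not show a loss of it. The p53 target list held 12 genes that rose and 4 that fell of 28 (12 and 5 adjusted over the list alone), was not called against the other genes (camera adjusted p = 0.217) and was higher on balance by itself (fry adjusted p = 0.00800).

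By size, the 10 largest rises under the naming rule were Lce1f (2.46 ± 0.20), Lce1h (2.42 ± 0.19), Cdkn1a, the TNF-family ligand Tnfsf15 (1.98 ± 0.15), Crct1 (1.82 ± 0.19), Angpt4 (1.62 ± 0.17), Serpinb9b (1.58 ± 0.12), Acta1 (1.57 ± 0.061), Gldn (1.55 ± 0.23) and the platelet chemokine gene Ppbp (1.53 ± 0.13). Lce1f and Lce1h belong to a cluster of near-identical genes of the skin barrier, between which the counting could have split reads, and stood at 4.23 and 15.7 CPM with p21. The largest falls were the growth arrest gene Gas1 (-1.58 ± 0.15), Sapcd2 (-1.57 ± 0.17), Ndufa4l2 (-1.37 ± 0.23), Ptn, which encodes pleiotrophin (-1.26 ± 0.29), the spindle genes Aspm (-1.25 ± 0.046) and Ska1 (-1.24 ± 0.12), the urea transporter gene Slc14a1 (-1.24 ± 0.15), the phosphatase gene Cdc25b (-1.21 ± 0.11), Pif1 (-1.17 ± 0.14) and the kinesin gene Kif14 (-1.16 ± 0.065). Across all genes, 5681 passed an edgeR quasi-likelihood test at an adjusted p under 0.05, 2816 higher and 2865 lower with p21. Of these, 275 were at least 2-fold higher and 111 at least 2-fold lower by estimate, a size that the test itself does not cover. Tested against a 1.5-fold change, glmTreat called 266. The split between directions moved with the scaling, to 2173 higher and 3734 lower when libraries were scaled by their totals alone. The libraries of both groups did not overlap for 49.1% of genes, where chance gives 10% for unpaired libraries, a value that leaves the pairing by replicate number aside.

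**Figure D2:**
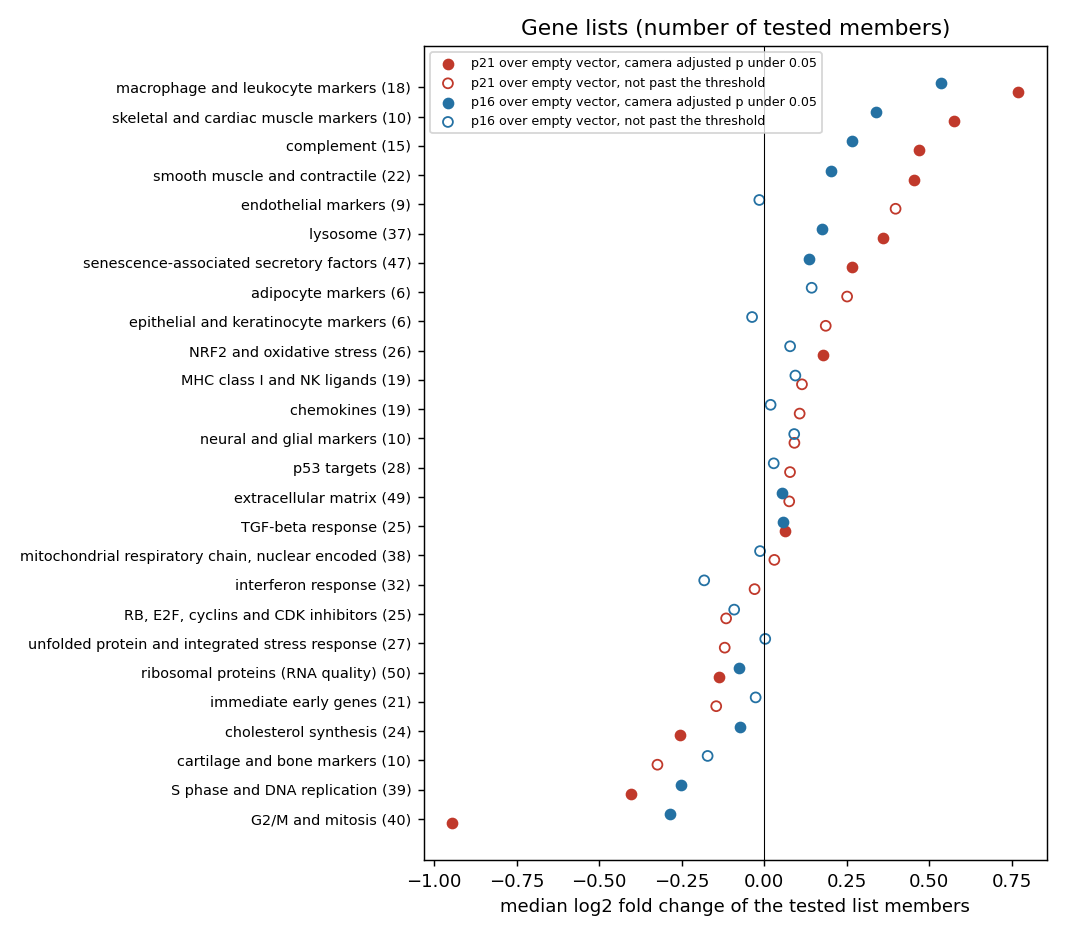
Median log2 fold change of the tested members of 26 gene lists (vertical axis, with the number of tested members) for p21 and p16 over the empty vector, filled where the camera adjusted p was under 0.05. The G2/M and mitosis list lies lowest in both, at -0.95 with p21 and -0.29 with p16.

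The comparison of p16 with the empty vector gave changes in many of the same lists. Of 40 G2/M and mitosis genes, 37 fell and 0 rose (39 and 0 adjusted over the list alone), with a median log2 fold change of -0.29 (camera adjusted p = 4.76e-38, but adjusted p = 0.0569 with an estimated correlation). Ccna2 went from 107 to 77.0 CPM (-0.47 ± 0.044) and Mki67 from 245 to 175 CPM (-0.48 ± 0.048). Of 39 S phase and DNA replication genes, 29 fell and 1 rose (33 and 1 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.74e-22, and adjusted p = 0.0480 with an estimated correlation). Mcm5 changed by -0.38 ± 0.041. Ccnd2 and Ccnd1, which encode D-type cyclins, rose by 0.49 ± 0.038 and 0.38 ± 0.057 in a list of RB, E2F, cyclin and CDK inhibitor genes where 6 rose and 7 fell of 25 (6 and 10 adjusted over the list alone, camera adjusted p = 0.680). Ccnd1 shares 21.9% of its exon bases with a gene annotated on the opposite strand, and the counts do not separate their reads.

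Smooth muscle and contractile genes were higher with p16 as well, 12 of 22 rising and 0 falling (15 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 1.88e-15, and adjusted p = 0.0156 with an estimated correlation). The intermediate filament gene Des rose from 87.4 to 145 CPM (0.73 ± 0.092), and Hspb1, a small heat shock protein gene on that list, from 178 to 271 CPM (0.61 ± 0.034). Skeletal and cardiac muscle markers moved with them: 2 of 10 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 0.00184, but adjusted p = 0.0741 with an estimated correlation). Acta1 rose from 132 to 191 CPM (0.53 ± 0.060). Chrna1 also passed (0.63 ± 0.18), a call lost by limma-voom and without each of the control replicates and p16 replicates 1 and 2 in turn (highest edgeR adjusted p = 0.152). Of 37 lysosome genes, 21 rose and 0 fell (26 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 1.92e-15, but adjusted p = 0.0741 with an estimated correlation). The autophagy receptor gene Sqstm1 changed by 0.31 ± 0.034. Among 47 secretory factors, 14 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 1.90e-06, and adjusted p = 0.0480 with an estimated correlation). Inhba changed by 0.40 ± 0.050. No chemokine gene of 19 tested passed the edgeR test in either adjustment, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (camera adjusted p = 0.763). With the replicate block 3 passed, Ccl2 (0.14) and Ccl7 (0.30) higher and Cxcl5 (-0.28), named after its value was seen, lower with p16. Ccl7 also passed with replicates 1 and 2 alone (edgeR adjusted p = 0.0346) and Ccl2 without control replicate 1 (edgeR adjusted p = 0.0462). Complement genes rose in 2 of 15 cases and fell in 0, in both adjustments (camera adjusted p = 0.00547, but adjusted p = 0.197 with an estimated correlation). The camera call of this list was lost without control replicate 2 (adjusted p = 0.0511) and without p16 replicate 3 (adjusted p = 0.0592). Clu rose from 3.81 to 8.21 CPM (1.10 ± 0.14). Beside these groups, the macrophage and leukocyte markers had a median of 0.54 with 0 of 18 markers past the edgeR test in either adjustment, 4 with an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom (camera adjusted p = 0.00248, but adjusted p = 0.508 with an estimated correlation and 0.174 without p16 replicate 3). With the replicate block 6 markers passed, all higher with p16. Csf1r passed without control replicate 3 (edgeR adjusted p = 0.0439) and Tyrobp, named after its value was seen, without p16 replicate 1 (edgeR adjusted p = 0.0408).

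The 10 largest rises with p16 under the naming rule were Cdkn2a, the inducible heat shock genes Hspa1a (2.47 ± 0.13) and Hspa1b (1.17 ± 0.12), Lce1f (1.49 ± 0.21), Clu, Lce1h (1.07 ± 0.19), Dcaf12l1 (1.03 ± 0.25), the phospholipase gene Pla1a (1.02 ± 0.14), Tnfsf15 (0.93 ± 0.16) and Parm1 (0.93 ± 0.12). Hspa1a rose from 6.45 ± 0.513 to 35.7 ± 6.96 CPM and its near-identical neighbour Hspa1b from 38.7 ± 3.64 to 87.1 ± 14.7 CPM, so the share of each is uncertain, and 5 of 22 other heat shock genes rose. The largest falls were the cartilage proteoglycan gene Acan (-0.95 ± 0.22), Enpp2, which encodes autotaxin (-0.91 ± 0.11), Slc14a1 (-0.91 ± 0.14), the interleukin 33 receptor gene Il1rl1 (-0.81 ± 0.18), Gas1 (-0.77 ± 0.14), Phf19 (-0.75 ± 0.091), the transcription factor gene Runx3 (-0.73 ± 0.12), Ankle1 (-0.73 ± 0.21), Tmem26 (-0.70 ± 0.13) and Ndnf (-0.68 ± 0.14). Leaving out 1 library ended the call of Acan (without p16 replicate 1 or 2, highest edgeR adjusted p = 0.0751) and of Il1rl1 (without control replicate 1, edgeR adjusted p = 0.0657). It also ended the call of Dcaf12l1 without control replicate 1 or 2 or p16 replicate 1 or 3 (highest edgeR adjusted p = 0.0855, and not called by limma-voom either) and that of Ankle1 without control replicate 1 or 2 or any p16 library (highest edgeR adjusted p = 0.162).

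In all, 1616 genes passed the edgeR test with p16, 825 higher and 791 lower. Of these, 40 and 11 changed at least 2-fold by estimate, and glmTreat called 2 genes against a 1.5-fold change. With the replicate number as a block 3044 genes passed, including all of these 1616. Scaled by library totals alone, the split was 617 higher and 1235 lower. The count fell to 826 without control replicate 1, 921 without control replicate 2, and 1070, 759 and 984 without p16 replicate 1, 2 or 3. The libraries of both groups did not overlap for 32.7% of genes, where chance gives 10% for unpaired libraries. Ribosomal protein genes fell in 4 of 50 cases and rose in 0 (22 and 0 adjusted over the list alone, median -0.077, camera adjusted p = 1.63e-06, but adjusted p = 0.508 with an estimated correlation). The NRF2 and oxidative stress list passed as a group with the replicate block and not in the main fit (camera adjusted p = 0.0221 against 0.104, but adjusted p = 0.508 with an estimated correlation and no block). Without a block it also passed with replicates 1 and 2 alone (camera adjusted p = 0.0132) and without p16 replicate 3 (0.0319). In the main fit 3 of its 26 genes rose and 1 fell, in both adjustments.

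The direct comparison of p21 with p16 tests where the libraries of both groups differ. A batch of the p16 libraries, if they were made apart, would enter it and could not be told apart from p16. All 40 G2/M and mitosis genes were lower with p21 than with p16, in both adjustments, with a median log2 difference of -0.64 (camera adjusted p = 2.02e-136, and adjusted p = 0.00693 with an estimated correlation). Plk1, the mitotic kinase, stood at 51.2 ± 3.01 CPM with p21 and 84.3 ± 0.850 CPM with p16 (-0.72 ± 0.047), and Racgap1, a regulator of cytokinesis, differed by -0.65 ± 0.040. Of 39 S phase and DNA replication genes, 17 were lower and 1 higher with p21 (25 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 1.81e-09, but adjusted p = 0.159 with an estimated correlation). Smooth muscle and contractile genes were higher with p21 in 14 of 22 cases and lower in 0 (16 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 1.44e-15, and adjusted p = 0.00693 with an estimated correlation). Myh11 differed by 0.68 ± 0.047 and Acta1, of the skeletal list, by 1.04 ± 0.060. Lysosome genes were higher in 19 of 37 cases and lower in 0 (21 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 3.04e-14, but adjusted p = 0.159 with an estimated correlation). Ctsd differed by 0.41 ± 0.038. Cholesterol synthesis genes were lower in 13 of 24 cases and higher in 0 (17 and 0 adjusted over the list alone, camera adjusted p = 1.87e-07, but adjusted p = 0.159 with an estimated correlation). NRF2 and oxidative stress genes were higher in 9 of 26 cases and lower in 0 (12 and 1 adjusted over the list alone, camera adjusted p = 1.10e-04, but adjusted p = 0.159 with an estimated correlation). Hmox1 differed by 0.67 ± 0.053 and Nqo1, a quinone reductase gene, by 0.41 ± 0.049. Ribosomal protein genes were lower in 3 of 50 cases and higher in 0 (9 and 0 adjusted over the list alone, median -0.061, camera adjusted p = 6.87e-04, but adjusted p = 0.682 with an estimated correlation).

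Of 47 secretory factors, 11 were higher and 2 lower with p21 than with p16 (12 and 5 adjusted over the list alone, camera adjusted p = 0.0200, but adjusted p = 0.222 with an estimated correlation and 0.0949 without p21 replicate 1). The adhesion gene Icam1 was higher (1.01 ± 0.14) and Igfbp5 lower (-1.0 ± 0.092). Chemokine genes gave no edgeR call among 19 in either adjustment, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Cxcl14 stood at 30.8 CPM with p21 and 25.3 CPM with p16 (edgeR adjusted p = 0.157, 0.00176 with the replicate block, 0.0225 with replicates 1 and 2 alone and 0.0471 without p21 replicate 3). With the block 3 chemokine genes passed, Ccl20 (0.68) and Cxcl14 higher and Cxcl12 (-0.13), named after its value was seen, lower with p21. The macrophage and leukocyte markers gave 0 edgeR calls of 18 in either adjustment, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (median 0.26, camera adjusted p = 0.203, but 0.00140 without p16 replicate 3 and 0.0203 with replicates 1 and 2 alone). Lyz2 passed with the replicate block (0.38), and Lyz2 and Csf1r passed with replicates 1 and 2 alone (0.55 and 0.58), each higher with p21. Complement genes gave 0 edgeR calls of 15 in either adjustment, 5 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and as a list passed with the replicate block and without p16 replicate 3 but not in the main fit (camera adjusted p = 0.0409, 0.0325 and 0.139, but adjusted p = 0.432 with an estimated correlation in the main fit). With the block 5 members passed, among them C1qtnf1, Masp1 and Cd59a higher and Clu lower with p21, of which C1qtnf1 and Masp1 are named after their values were seen. Masp1 passed with replicates 1 and 2 alone, Cd59a without p21 replicate 2 (edgeR adjusted p = 0.0351) and Masp1 without p21 replicate 3 (edgeR adjusted p = 0.0203).

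The largest differences under the naming rule were, besides the delivered genes, Lce1h (1.35 ± 0.17), Tnfsf15 (1.05 ± 0.14), Acta1, Icam1, Crct1 (1.0 ± 0.18), Lce1f (0.97 ± 0.18), Serpinb9b (0.92 ± 0.12), Nebl (0.87 ± 0.20) and Gldn (0.86 ± 0.22) on the side of p21. On the side of p16 they were Hspa1a (-2.59 ± 0.13), Ndufa4l2 (-1.25 ± 0.23), Igfbp5, Hspa1b (-0.97 ± 0.12), Sapcd2 (-0.95 ± 0.18), the kinesin gene Kif20b (-0.83 ± 0.063), Fam64a (-0.82 ± 0.044), Gas1 (-0.82 ± 0.15) and Ndrg1 (-0.81 ± 0.082). The call of Nebl was lost without p21 replicate 1 (edgeR adjusted p = 0.0575) and that of Gldn without p21 replicate 1 or 2 or p16 replicate 2 or 3 (highest edgeR adjusted p = 0.0865). In total 1858 genes differed by edgeR, 875 higher and 983 lower with p21, and 46 and 12 of them by an estimated 2-fold or more. Against a 1.5-fold change glmTreat called 5. In all, 3214 passed with the replicate block, including all of these 1858. Library totals alone gave 735 higher and 1254 lower. The count fell to 1078 without p21 replicate 1, 1074 without p16 replicate 1 and 1151 without p16 replicate 2. The libraries of both groups did not overlap for 31.2% of genes, where chance gives 10% for unpaired libraries.

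Most genes called with p16 were also called with p21, in the same direction. Leaving out both delivered genes, 777 genes were higher and 775 lower in both comparisons with the empty vector, 96.1% of the 1615 called with p16. Independent lists of the observed lengths would share 163 and 159. Simulated groups without any change gave a mean of 0.06 and 0 such genes. Almost no gene can pass in groups without a change, so these simulated counts are no baseline for the overlap. The 2 genes called in opposite directions were Hsph1, a heat shock gene (log2 fold change -0.22 with p21 and 0.16 with p16), and Fam132b, which encodes erythroferrone (-0.32 and 0.30), both named after their values were seen. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.746 and Spearman's rho = 0.777. The shared controls alone gave 0.502 and 0.451 in simulation. Their covariance was 0.0866 against a simulated 0.0216. The simulation had no pairing by replicate number and took its spread from the fit without a block, so the simulated covariance can be too high. The 3 controls could not be split into parts of at least 2 libraries, so part of the overlap may come from the shared controls. Of the 1552 genes called in both, 1461 had the larger fold change with p21. The direct comparison called 787 of the genes called in both as further from the control with p21. Of the 4125 genes called with p21 and not with p16, it called 1001 different between p21 and p16.

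**Figure D3:**
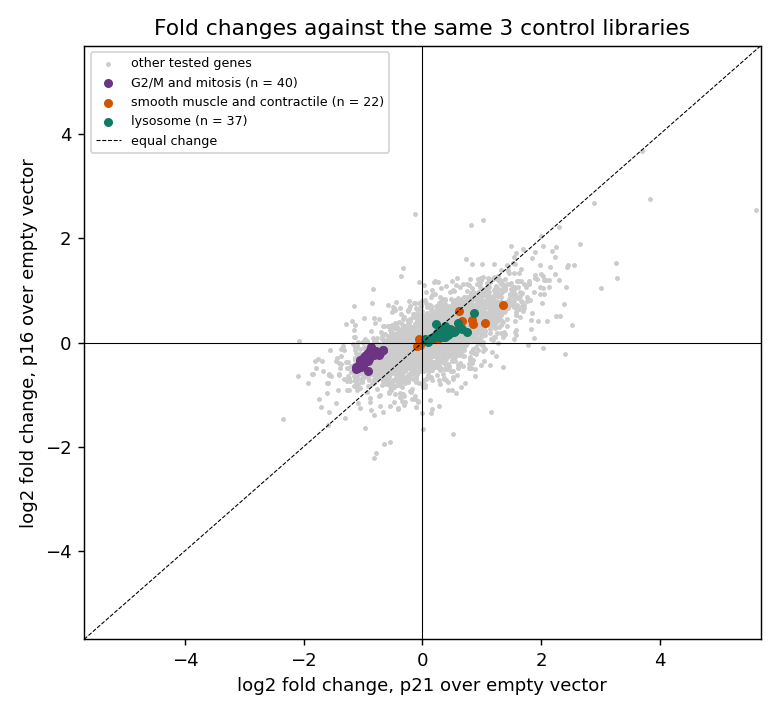
Log2 fold change over the empty vector with p21 (horizontal axis) and p16 (vertical axis) for all tested genes except the delivered ones, 1 point per gene, with 3 gene lists in colour and a dashed line of equal change. The G2/M and mitosis genes lie below 0 on both axes, with medians of -0.95 and -0.29, and the fold changes correlate at r = 0.746 across genes.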

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

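The counts of other splits and the fit of replicates 1 and 2 alone were tests chosen after the data were seen. Under DESeq2 size factors, library totals, the removal of both delivered genes, no filter, DESeq2, limma-voom and fits of only the groups compared, each count of called genes stayed within 1.5 times its value, and so it did with replicates 1 and 2 alone (5520 genes with p21, 1515 with p16 and 1900 in p21 against p16). With the replicate block 6856 genes passed with p21, 3044 with p16 and 3214 in p21 against p16. Against a 1.5-fold change glmTreat called 266, 2 and 5, a stricter question by construction. Leaving out 1 library gave 4617 to 5409 genes with p21, 759 to 1167 with p16 and 1074 to 1782 in p21 against p16, with fewer samples. Called lists numbered 2, 3 and 2 with an estimated correlation, against 12, 12 and 11, and 11 to 12, 11 to 13 and 9 to 13 without 1 library. Genes called in both comparisons with the empty vector fell from 1552 to 585 at an adjusted p under 0.01, by construction, and numbered 1784 with library totals. The delivered genes kept their calls in every fit that held them, and no named gene or list reversed where it was called in either fit. Lists called in neither could change direction, as the immediate early list did with p16 and the replicate block. For other changes the cause was not tested.

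Of the named genes called, 100 of 114 with p21, 57 of 80 with p16 and 61 of 78 in p21 against p16 kept their call whichever library was left out. These fits had no block, so differences between the replicate numbers entered their spread. The replicate block added 6, 21 and 20 named genes and ended the call of Sox10 with p21. It added the list calls given beside their lists and changed no other list call. List calls also came up for interferon genes with p16, with replicates 1 and 2 alone and without control replicate 2 (camera adjusted p = 0.0428 and 0.0262), and for MHC class I genes without p16 replicate 1 (0.0462). In p21 against p16 the respiratory chain passed without both delivered genes, p21 replicate 2 or p16 replicate 2 (0.0438, 0.00869 and 0.0286). By fry, which compares no list with other genes, 16, 12 and 11 lists passed. It added with p21 the RB and p53 lists, chemokines (adjusted p = 0.00800), unfolded protein response (0.0258) and cartilage (0.0169), with p16 NRF2 and adipocyte genes (both 0.0358), and in p21 against p16 chemokines (0.0436). With fry the ribosomal list lost its call in p21 against p16 (adjusted p = 0.0592), the matrix list with p16 (adjusted p = 0.0982), and the leukocyte list with p21 and p16 (adjusted p = 0.0588 and 0.213).

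The 6 libraries of a comparison make 10 splits, of which 4 part all 3 pairs and 6 part 1, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many called genes: 5681 with p21, 1616 with p16 and 1858 in p21 against p16, and the highest of the other splits gave 0. Every other split mixes libraries of both groups on each side, so the difference between the groups swells its spread. Its 0 calls therefore add no evidence.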

Other observations

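The tests of reads moved between near-identical copies were chosen after the folds were seen, and the added heat shock and histone lists were made after the data were examined. Genes of the integrated stress response went both ways with p21: 5 of 27 rose and 12 fell (5 and 13 adjusted over the list alone, camera adjusted p = 0.217). Nupr1, a stress-induced regulator, rose from 95.9 to 149 CPM (0.64 ± 0.071), while the serine and one-carbon genes Psat1 and Shmt2 changed by -0.38 ± 0.047 and -0.42 ± 0.059. With p16 3 rose and 2 fell (camera adjusted p = 0.994). With p21 against p16 4 were lower and 0 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.0303, but adjusted p = 0.333 with an estimated correlation). This last call was lost without p21 replicate 1 or 2 or p16 replicate 2 (adjusted p = 0.0949, 0.0661 and 0.0743). Of 21 immediate early genes 4 rose and 8 fell with p21 (4 and 9 adjusted over the list alone, camera adjusted p = 0.640). The phosphatase gene Dusp1 changed by 0.67 ± 0.051 and the transcription factor gene Egr3 by -0.81 ± 0.098. With p16 the list had a median of -0.026 and a mean of -0.009 but a test direction of up (camera adjusted p = 0.994). Of 19 MHC class I and NK ligand genes 4 rose and 2 fell, in both adjustments, with p21 (camera adjusted p = 0.435). B2m, the light chain of MHC class I, changed by 0.30 ± 0.046. The interferon list gave 2 rises and 2 falls of 32 with p21 (1 and 1 adjusted over the list alone), a median of -0.029 against a mean of 0.016 and a test direction of up (camera adjusted p = 0.941). Of 38 nuclear genes of the respiratory chain 9 rose and 3 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.285).

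With p16, matrix genes rose in 14 of 49 cases and fell in 5 (19 and 6 adjusted over the list alone, camera adjusted p = 9.31e-04, but adjusted p = 0.463 with an estimated correlation). The basement membrane collagen genes Col4a1 and Col4a2 changed by 0.36 ± 0.037 and 0.35 ± 0.039. TGF-beta response genes rose in 8 of 25 and fell in 0 (8 and 2 adjusted over the list alone, camera adjusted p = 0.00184, but adjusted p = 0.197 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 24 and rose in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.00515, but adjusted p = 0.463 with an estimated correlation). In p21 against p16, 9 of 25 RB, E2F, cyclin and CDK inhibitor genes were lower and 2 higher (12 and 3 adjusted over the list alone, camera adjusted p = 0.0160, but adjusted p = 0.222 with an estimated correlation). Cdk2 differed by -0.30 ± 0.044. The skeletal muscle list passed there as well (median 0.18, camera adjusted p = 0.0192, but adjusted p = 0.159 with an estimated correlation). Its call was lost without p21 replicate 3 and with replicates 1 and 2 alone (adjusted p = 0.0570 and 0.0543). Cartilage and bone markers passed as a list with the replicate block and not in the main fit, with p21 (camera adjusted p = 0.0329 against 0.234) and with p16 (0.00120 against 0.118). In the main fit they had adjusted p = 0.482 and 0.406 with an estimated correlation. With p16 the list also passed with replicates 1 and 2 alone and without control replicate 1 (camera adjusted p = 0.0155 and 0.0213). With p21 4 of 10 fell and 0 rose, in both adjustments, and Sox9, a regulator of cartilage, changed by -0.52 ± 0.086. With p21 the endothelial (camera adjusted p = 0.581), epithelial (0.581), neural (0.499) and adipocyte (0.640) lists did not pass. The median and the test of the epithelial list with p16 (-0.037, up) and of the adipocyte list in p21 against p16 (0.073, down) differed in sign.

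Lysosome genes were higher with p21, by a median of 0.36 with the replicate block (camera adjusted p = 2.56e-19, but adjusted p = 0.0942 with an estimated correlation). RNA of leukocytes, which carry many lysosomes, as the whole source was argued against: with the marker sum as a covariate the median was 0.30 (camera adjusted p = 4.35e-12, but adjusted p = 0.178 with an estimated correlation), so a part from leukocytes stays open. The number of genes that rose went from 35 to 15 as the median SE grew from 0.039 to 0.093, and the fibroblasts may express some of the 18 markers themselves. Gene length and GC content were argued against too. Of 1000 sets of other genes matched on length, GC content and mean expression, 0% had a median as high (95th percentile 0.11). An effect of p21 on these genes stays open as a hypothesis.

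Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, rose in 13 of 34 cases and fell in 0 with p21 (median 0.48, unadjusted camera p = 2.79e-05, and p = 0.00290 with an estimated correlation), and with p16 6 rose and 0 fell (median 0.18, unadjusted camera p = 0.00121, and p = 0.00970 with an estimated correlation). For p21, length and GC content as the whole source were argued against, with 0.2% of sets matched on length, GC content and mean expression as high. But the matched sets themselves had a median of 0.19 (95th percentile 0.34) against 0.46 for the histone genes with the replicate block. A part that goes with length, GC content or expression level therefore stays open. Reads moved within the list would not raise its sum, which was 139 CPM in the lowest p21 library and 88.5 CPM in the highest control. With 13 rises and 0 falls, however, a higher sum was likely beforehand. Genes with many counts also dominate it, such as Hist1h2bc (mean log2 CPM 5.66, log2 fold change 0.81) and Hist1h1c (4.85 and 0.54), both named after their values were seen. Reads moved between near-identical copies with few counts would barely change the sum and stay open. More RNA without a poly(A) tail in the p21 libraries cannot be told apart from a change in the histone genes: 4 other such transcripts had a median of -0.068. This lies below 0.23, the bound set in advance from the histone median, but the median SE of these transcripts, 0.34, exceeds their SD of 0.16 and the distance, so that bound was too narrow, and an effect of p21, or of both inhibitors, stays open too.

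Hspa1a and Hspa1b rose with p16. Reads moved between both copies would raise 1 and lower the other, and both rose. Their sum therefore had to rise and is no separate test (109.7 CPM in the lowest p16 library, 47.8 CPM in the highest control). How the rise divides between the copies stays open. A heat shock response of the p16 cultures, from handling or from p16, stays open: of 22 other heat shock genes 5 rose and 1 fell, with a median of 0.028 and an unadjusted camera p of 0.00780, and p = 0.268 with an estimated correlation (with p21, a median of -0.054 and an unadjusted camera p of 0.738). The genes that rose included Hspb1 (0.61) and, named after its value was seen, Cryab (0.52), which are also expressed in contractile cells and rose with p21 too (0.61 and 0.93), where Hspa1a stood at -0.12 without a call. The others that rose with p16 were Bag3 (0.20), Hsph1 (0.16) and Dnajb4 (0.14), also named after their values were seen. Of these, Hsph1 fell with p21 (-0.22). Handling and p16 cannot be told apart in this design, which holds 1 set of p16 libraries.

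Beside Xist, the replicate 3 libraries held the Y-linked Ddx3y at 1.06 to 2.2 CPM against 51.8 to 67.8 CPM in the other libraries, and p21 replicate 1 held 413 Xist counts against 5 to 15 in the other replicate 1 and 2 libraries. The Y-linked Uty, Kdm5d and Eif2s3y were likewise low in the replicate 3 libraries only. These values argue against 1 shared cell source for all 3 replicates. Whether replicates 1 and 2 came from separate cultures stays open.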
